A study of Bos taurus with 40 samples.

How the data were processed

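The deposited values are spot intensity readings on a linear scale, 1 column per dye channel, between 369 and 63793. Per the labels' protocols, RNA was amplified with amino allyl nucleotides, coupled to Cy3 or Cy5 and spiked with control transcripts before processing. The scanner, the image software, the treatment of background and the rule that left cells blank are not given in the sources used here. Of all cells 57.39% were blank, and a blank was always shared by both channels of an array. Columns showed no normalization: the raw median log2 ratio of Cy5 to Cy3 ran from -0.66 to 0.77 between arrays. The spots are numbered 1 to 1040, and neighbouring odd and even numbers behaved as duplicates, with a correlation of 0.976 within such pairs and 0.128 when the pairing was shifted by 1. The duration of treatment is not given in the sources used here. All 40 columns were matched to a sample by its identifier in the column header, and the titles gave group, animal, array and dye.

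Samples were grouped by drug and stretch as their titles give them, and the muscle number in the title was taken as the animal. Values were taken to log2 without a pseudocount. Each array's log ratio was corrected by loess with a span of 0.4 and 4 robust iterations, and each array was shifted by its median deviation over the 193 spots measured on all 20 arrays. Scaling had not been part of the planned test and was added because the columns proved unscaled. Unscaled values were analysed as an alternative. Duplicate spots were averaged, or taken singly where 1 was blank, and the value of an RNA sample was the mean of its Cy3 and Cy5 values, both of which were required. A feature was tested if at least 3 animals had a value in each group, which left 190 of 520 pairs, 118 of them with all 20 RNA samples.

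Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the animal as a fixed block and the 4 treatments as levels. P values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05, and all tests were two-sided. Intervals are at 95%. Block correlations used statmod 1.5.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The procedure was tested on 1 simulated data set of 190 features. For stretch, 20 of 20 features changed by 1 on the log2 scale and 16 of 20 changed by 0.6 were called, and 1 unchanged feature was called. The same data set held no change for carbachol or the interaction, and 0 features were called for carbachol and 0 for the interaction. The simulated spread between RNA samples was drawn independently of the array. In the data, both channels of an array correlated at 0.797 in the fit for stretch. The simulation therefore does not show how comparisons that lie between arrays behave.

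The pairing by animal comes from the study's design, in which muscle of each animal received all treatments. Deviations from the group means correlated at 0.508 on average between samples of the same animal, with a lowest value of -0.0923, and at -0.127 between different animals. Much of that gap follows the array set, since different animals correlated at 0.323 within a set and at -0.427 across sets. The first principal component, with 40.9% of the variance, separated animals 4 and 5 from animals 1 to 3, which were on other arrays.

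Gene names came from the platform annotation at hand, which can be old and names 30 spots, that is 15 spot pairs of 14 genes, each of them matched by its gene number. All other spots are unnamed here. BRAF, ITGA6, RPL28, ITGA11, PRKCE and ITGA9 were tested. PRKAR1A was measured on 17 and 14 arrays for its 2 spots and missed the rule on values per group, and both CAV2 pairs, ACTN3, XPO7, ANAPC1, ITCH, MAP3K5 and PAK3 had values on at most 2 arrays. The groups, the tests, the 28 gene lists, the rule for named genes and part of the alternative settings were fixed before the data were examined. By that rule the text names up to 15 genes with the largest rise and 15 with the largest fall among those past the threshold, or the 10 with the smallest p where fewer than 10 passed, the members of each list with the smallest p, and a set of receptor, cytokine and contractile genes. With most features unnamed, the rule was applied to the named genes and to all called pairs, and unnamed pairs that did not pass are given only as single examples. Of the 28 lists, 2 had a measured gene and 0 had the 3 needed for a test of the list as a whole, which was not run. The muscarinic receptor, cytokine, contractile and housekeeping lists and the lists of other cell types had 0 measured genes, so that the cell makeup of the strips was not analysed here. Alternatives fixed in advance covered the block, the scaling, the dye, the array, dim spots, the variance model, a pseudocount of 50 and leaving out each animal, and others were added later.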

Results

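Gene expression was measured in strips of bovine tracheal smooth muscle that were kept in saline or in carbachol, an agonist of muscarinic acetylcholine receptors, and were either held without stretch or stretched cyclically. Carbachol was used at 1 µM, and stretch had an amplitude of 10% of muscle length at 1 Hz. Muscle of 5 animals went through all 4 treatments, which gave 20 RNA samples, 5 in each group. Each RNA was labelled once with Cy3 and once with Cy5, and the 40 labelled samples were hybridised in pairs to 20 custom oligonucleotide arrays. Arrays held values for 334 to 575 of the 1040 spots, and median intensity per column lay between 1046 and 6042.5. The number of animals limits the precision of every value. Of the 190 spot pairs with enough values for a test, 6 carried a gene name and 184 were unnamed, so that unnamed pairs are given by their spot numbers. Genome positions of the probes were not given in the sources used here.

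Stretched strips were compared with unstretched strips, averaged over saline and carbachol, to ask which transcripts respond to cyclic stretch. PRKCE, which encodes the epsilon isoform of protein kinase C, was higher in stretched strips by 0.63 ± 0.099 on the log2 scale (SE), a fold of 1.55, in 5 of 5 animals. In saline its mean log2 intensity was 10.6 ± 0.379 (SD, n = 5) without stretch and 11.19 ± 0.392 (SD, n = 5) with stretch. In carbachol it was 10.74 ± 0.366 (SD, n = 5) without stretch and 11.41 ± 0.486 (SD, n = 5) with stretch. The rise of PRKCE had an adjusted p of 3.69e-04 in limma. PRKCE was the 1 measured member of the list of G protein-coupled receptor signalling genes, so that its p adjusted over the list alone is its unadjusted limma p of 7.76e-06 and adds no further test.

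Another 5 unnamed spot pairs rose with stretch, and none of the 190 tested features fell (limma, adjusted p threshold 0.05). Spots 67 and 68 had the largest change among the 6, with a log2 rise of 2.53 ± 0.362 (SE, adjusted p = 1.82e-04), a fold of 5.79. Spots 35 and 36 rose by 2.00 ± 0.292 (SE, adjusted p = 1.82e-04), and spots 7 and 8 by 1.88 ± 0.192 (SE, adjusted p = 1.33e-05). Smaller log2 rises were measured for spots 955 and 956, at 1.22 ± 0.263 (SE, adjusted p = 8.95e-03), and for spots 93 and 94, at 0.42 ± 0.107 (SE, adjusted p = 0.0379). Each of these 5 pairs was higher in every animal in which it was measured, 4 of 4 animals for spots 7 and 8 and 5 of 5 for the others. The highest raw value of spots 67 and 68 was 62909, near 65535, the ceiling if readings were 16-bit, which the sources used here do not state. At an unadjusted p under 0.05 the stretch comparison held 22 features.

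**Figure D1:**
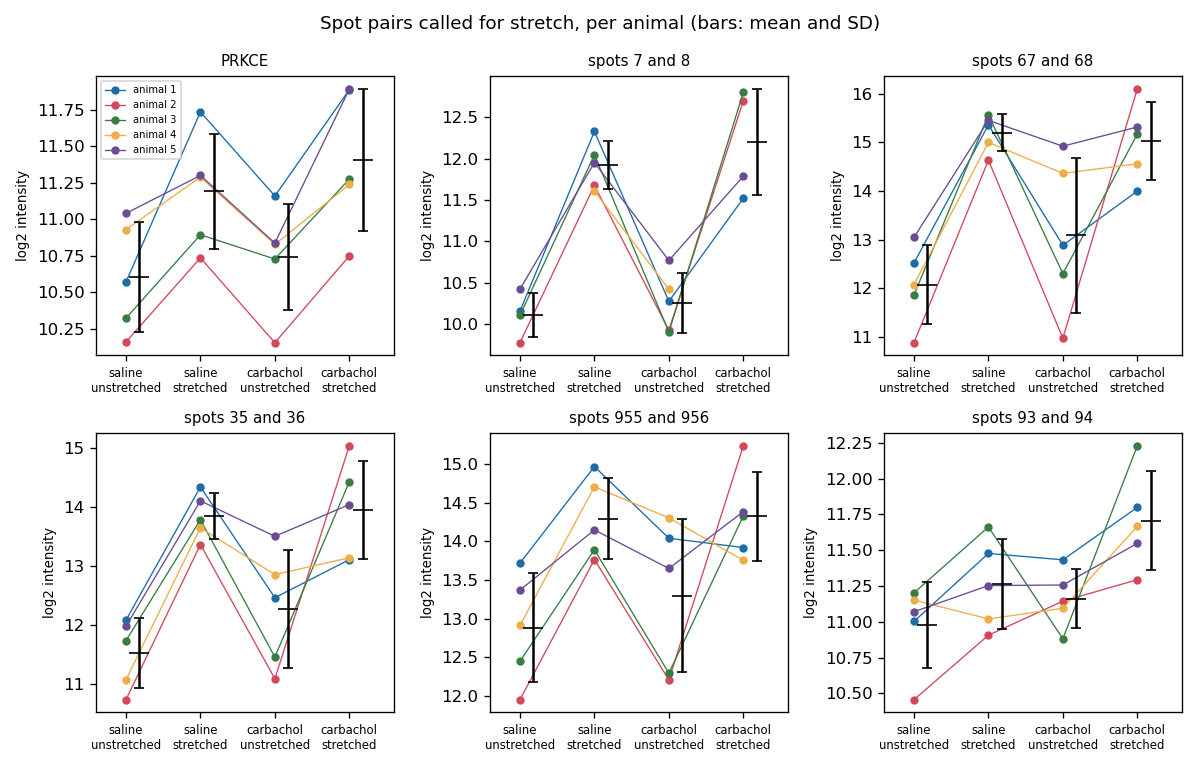
Normalised log2 intensity (y axis) of the 6 features called for stretch in the 4 groups (x axis), with 1 line per animal and the group mean and SD as black bars. In saline, mean PRKCE lies at 10.6 without stretch and at 11.19 with stretch, and spots 67 and 68 lie at 12.08 and 15.2.

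Animals 1 to 3 were hybridised on arrays 1 to 12 and animals 4 and 5 on arrays 13 to 20, so the change was also computed within each set. The mean log2 stretch change of PRKCE was 0.70 in animals 1 to 3 and 0.52 in animals 4 and 5. For spots 67 and 68 these means were 3.23 and 1.48, for spots 35 and 36 2.41 and 1.38, and for spots 7 and 8 2.16 and 1.27, the latter from animal 5 alone. They were 1.57 and 0.69 for spots 955 and 956, and 0.54 and 0.23 for spots 93 and 94. In animal 1 the changes of spots 67 and 68, 35 and 36, and 955 and 956 were 1.98, 1.45 and 0.564. These lay nearer to animals 4 and 5 than to animals 2 and 3, which did not hold for PRKCE (0.948 in animal 1). In a limma test of the difference between the sets, 0 of 118 features passed for stretch, with 2 at an unadjusted p under 0.05. Without the replicate block the adjusted p of PRKCE was 0.0746, and from Cy5 values alone it was 0.248, within a range of 2.6e-05 to 0.999 over all alternatives. The call of spots 93 and 94 was lost without animal 1, 3, 4 or 5, with adjusted p values of 0.139, 0.17, 0.0727 and 0.109, and that of spots 955 and 956 without animal 3 (0.128).

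The other named genes did not pass the stretch test. The integrin alpha subunits ITGA9 and ITGA6, which are receptors for extracellular matrix, had log2 changes of 0.15 ± 0.092 and 0.10 ± 0.114 (SE), with adjusted p of 0.574 and 0.847. They were the 2 measured members of the focal adhesion and integrin list, of which 0 passed over all features and 0 when adjusted over the list alone. The changes of ITGA11, the kinase BRAF and the ribosomal protein gene RPL28 were 0.05 ± 0.112, -0.03 ± 0.149 and -0.00345 ± 0.081 (SE), each with an adjusted p of 0.983 or higher.

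**Figure D2:**
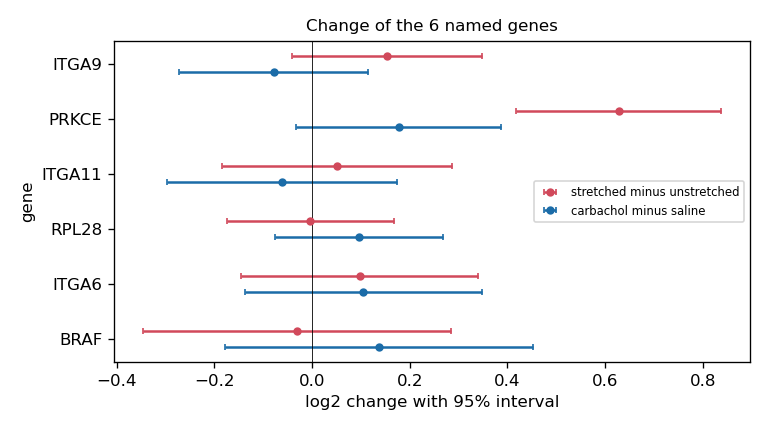
Log2 change (x axis) with its 95% interval for the 6 named genes (y axis), for stretched minus unstretched strips in red and carbachol minus saline in blue. The stretch interval of PRKCE runs from 0.42 to 0.84, and the other 11 intervals include 0.

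The stretch response was then measured in each drug state. In animals 1, 4 and 5 these changes could be read only between arrays, since saline stretched strips shared their arrays with carbachol unstretched strips. In animals 4 and 5 the average over both drug states was free of this limit. In saline, 4 features rose and 0 fell: spots 67 and 68 by 3.13 ± 0.512 (SE), spots 35 and 36 by 2.32 ± 0.413, spots 7 and 8 by 1.83 ± 0.279 and PRKCE by 0.59 ± 0.141 on the log2 scale. In carbachol, 2 features rose and 0 fell: spots 7 and 8 by 1.93 ± 0.279 (SE, adjusted p = 9.84e-04) and PRKCE by 0.67 ± 0.141 (SE, adjusted p = 0.0175). Both had also passed in saline. Spots 67 and 68 had a change of 1.94 ± 0.512 (SE) in carbachol with an adjusted p of 0.0697 in limma. Its per-animal values were 1.11, 5.13, 2.87, 0.197 and 0.395, a mean of 3.04 in animals 1 to 3 and 0.30 in animals 4 and 5. Those of spots 35 and 36 were 0.644, 3.94, 2.96, 0.285 and 0.537, averaging 2.52 and 0.41. For both pairs animal 1 lay nearer to animals 4 and 5 than to animals 2 and 3, so the split did not follow the array sets. The differences between the sets, -2.74 and -2.10, did not pass in limma (adjusted p = 0.162 and 0.232). The count in carbachol was 6 without animal 2, 4 without animal 4, 1 without animal 3, 1 without animal 5 and 1 without the replicate block.

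Whether carbachol altered the stretch response was tested by the interaction of both factors. The rise of PRKCE in carbachol exceeded that in saline by 0.08 ± 0.199 (SE), which did not pass (limma, adjusted p = 0.956), with a 95% interval of -0.34 to 0.50 on the log2 scale. ITGA11 had an interaction of 0.58 ± 0.223 (SE) with an adjusted p of 0.696, and BRAF one of 0.57 ± 0.299 with an adjusted p of 0.819. Both were highest in animal 1, at 1.81 and 2.28, and without it they were 0.275 and 0.145. The BRAF mean was 1.18 in animals 1 to 3 and -0.34 in animals 4 and 5, a difference that did not pass (limma, adjusted p = 0.144). In the test of the difference between the sets, 0 of 118 interactions passed, with 28 at an unadjusted p under 0.05. No feature passed (0 of 190 in limma, 9 at an unadjusted p under 0.05). Spots 319 and 320 had the smallest p, with an interaction of 1.15 ± 0.32 (SE) and an adjusted p of 0.423. In animals 1, 4 and 5 the interaction could be read only between arrays. The median SE of the interaction was 0.241, against 0.117 for stretch. The gap follows from the comparison itself, since the interaction is a difference of stretch changes and the stretch comparison their mean.

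Carbachol was compared with saline, averaged over both stretch states, to ask which transcripts respond to muscarinic stimulation. No named gene passed. PRKCE had a log2 change of 0.18 ± 0.099 (SE, adjusted p = 0.976), BRAF 0.14 ± 0.149, ITGA6 0.11 ± 0.114, RPL28 0.10 ± 0.081, ITGA11 -0.06 ± 0.112 and ITGA9 -0.08 ± 0.092. Over all features 0 of 190 passed in limma, 11 had an unadjusted p under 0.05, and the smallest adjusted p was 0.323. Spots 311 and 312 had the lowest change, -0.51 ± 0.156 (SE), and spots 981 and 982 the smallest p, at -0.39 ± 0.111 (SE). In unstretched strips 0 features passed, with 7 at an unadjusted p under 0.05, and in stretched strips 0 passed, with 15. Within 1 stretch state, the carbachol change of animals 1, 4 and 5 could be read only between arrays. Fits on arrays that counted both labellings of an RNA separately called 16 and 20 features for carbachol. In simulated data, a log2 change of 0.6 was called in 16 of 20 changed features for stretch. Carbachol changes of that size were not simulated.

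**Figure D3:**
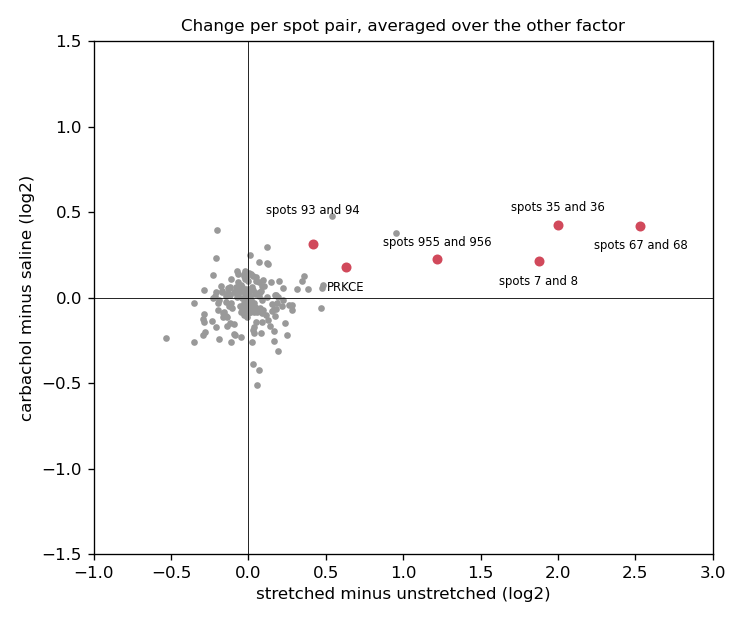
Log2 change of stretched minus unstretched strips (x axis) against carbachol minus saline (y axis) for 190 features, with the 6 called for stretch in red. The stretch changes reach 2.53, while the carbachol changes lie between -0.51 and 0.48.

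Strips given both carbachol and stretch were compared with untreated strips in saline. PRKCE was higher by 0.81 ± 0.141 on the log2 scale (SE, adjusted p = 1.17e-03), a fold of 1.75. In all, 7 features rose and 0 fell. The pairs with the largest rises were spots 67 and 68 at 2.95 ± 0.512 (SE), spots 35 and 36 at 2.43 ± 0.413 and spots 7 and 8 at 2.09 ± 0.287. Spots 955 and 956 rose by 1.44 ± 0.372, spots 55 and 56 by 1.01 ± 0.274 (adjusted p = 0.0487) and spots 93 and 94 by 0.73 ± 0.152. Raw values of spots 55 and 56 reached 61872 with both treatments and 51396 in untreated strips, against 65535, the ceiling if readings were 16-bit. The call of spots 55 and 56 was lost in 16 of 25 alternatives, with adjusted p values of 0.0759, 0.236 and 0.143 without animal 2, 4 or 5. That of spots 955 and 956 was lost in 11, with 0.0938, 0.225 and 0.105 without animal 2, 3 or 5, and that of spots 93 and 94 in 9. ITGA6, RPL28, BRAF, ITGA9 and ITGA11 did not pass, with changes between -0.01 and 0.20. This comparison uses strips that also enter the stretch comparison, so its calls are not independent of it. Without the replicate block 3 features passed, and the adjusted p of PRKCE was 0.134, within a range of 7.07e-05 to 0.681 over its alternatives.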

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

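The tests weighing the dimmer carbachol channel and the comparison between sets of animals were chosen after the results were seen. The tests for outlying samples were not. Among 28 groups of per-animal changes or column medians, 0 held a sample far from the others by Dixon's criterion. The carbachol change in unstretched strips differed between animals 4 and 5 and animals 1 to 3 for 2 of 118 features in a limma test of the difference, with 15 at an unadjusted p under 0.05. Spots 533 and 534 differed by -1.19 and spots 901 and 902 by -1.36 on the log2 scale, each with an adjusted p of 0.0496. These animals were also on different arrays, so animal and array set are confounded in that difference. In animals 1, 4 and 5 this change could moreover be read only between arrays, and the fit has no term for the array.

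Of the spots outside the tested features, 45 had values on at least 7 of arrays 13 to 20 and on at most 1 of arrays 1 to 12. Their median log2 intensity was 12.9, and all 45 sat among the first or last 3 positions of runs of 20 spot numbers. Which sequences they carry is not given in the sources used here. They offer a second reference for a shift that the scaling removes: on 8 of 8 arrays from 13 to 20 the carbachol channel was dimmer, by a mean log2 difference of -0.45 ± 0.145 (SD over 4 dye swaps). These 8 arrays are 4 dye-swapped pairs of strips. On the 6 earlier arrays that pair carbachol with saline, 3 were dimmer, with a mean of -0.03. Cy5 was the dimmer channel on all 6, and the 3 were those with carbachol in Cy5, so this count follows the dye.

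A difference in labelling or scanner gain would move all spots of a channel alike. The mean shift was -0.45 for the other spots but -0.15 ± 0.0886 (SD over 4 dye swaps) for the 45 spots. Their difference, -0.30 ± 0.0587 (SD over 4 dye swaps), is part of the -0.45 and argues against gain as the whole cause. Brightness of the 45 spots does not account for all of it either, since other spots of matched brightness still differed from them by -0.24 ± 0.0754 (SD over 4 dye swaps). Less gene RNA per spiked transcript in carbachol strips may explain it if the 45 spots are the spiked controls. This cannot be told apart from an effect of their position, because only 1.3% of their values were measured on arrays 1 to 12 and their identity is open. Centred on those spots, the median carbachol change in animals 4 and 5 was -0.23, with 132 of 163 features lower and 0 called.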

How the results depend on the processing

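Chosen after seeing the data were the unscaled values, the median in place of loess, normexp, 1 dye channel sufficing, single spots of a pair, the separate array sets, the 45-spot centring and the fit with array effects removed. The 859 results hold only called pairs and named genes, called or not: 71 calls lost, 27 for stretch, 0 reversed or gained. Without the replicate block, counts were 4 for stretch, 3 for stretch in saline, 1 for stretch in carbachol and 3 for both against control; it changed no other count. Median centring gave 1 for stretch in carbachol and 4 for both against control, and quantile normalization 1 and 4, with 1 for carbachol in stretched strips and 4 higher and 1 lower for stretch. Cy3 alone gave 3 for both against control, and Cy5 alone 3, with 3 for stretch. Unscaled values gave 4 for both against control and moved the median carbachol change to -0.21 and the median interaction to 0.24. Median centring moved the median interaction to -0.13 and Cy3 alone to 0.11.

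Within-array ratios called 16 features for carbachol, 43 for stretch (24 higher, 19 lower), 15 for carbachol in stretched strips, 12 for stretch in saline, 4 for stretch in carbachol and 23 for both. The fit of 40 channels with arrays as random block called 20, 60 (35 higher, 25 lower), 16, 41, 11 and 33, and 1 for carbachol in unstretched strips. Both treat labellings of an RNA as independent. With array effects removed and 1 value per RNA, 7 features were called for stretch, including all 6, 4 for stretch in saline, 8 for both, and 0 for carbachol and for carbachol in stretched strips, so most of that excess came with this construction. For stretch in carbachol it called 5, which the construction does not account for. Animals 1 to 3 alone gave 4 for both against control. Animals 4 and 5 alone gave 2 for carbachol, 3 for stretch, 5 for the interaction, 5 for carbachol in unstretched strips, 4 for stretch in carbachol and 2 for both. Centring these animals on the 45 spots gave 0 for stretch (also in saline and in carbachol) and for both. Leaving out each animal gave 4 to 7 for stretch, 3 to 4 in saline, 1 to 6 in carbachol, 5 to 7 for both, and 0 for the others. No cause was established for these shifts.

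Of the 6 stretch features, spots 7 and 8 lost the call in 0 of 23 alternatives, which lack animals 4 and 5 alone and the 45-spot centring (no value in animal 4). In that centring the other 5 lost theirs, at changes close to those without it (PRKCE 0.537 and 0.522), where 3 of them had already lost it. Over 25 alternatives, spots 35 and 36 and spots 67 and 68 lost it in 1 each, PRKCE in 4, spots 955 and 956 in 6, and spots 93 and 94 in 15. For both against control, spots 55 and 56 lost it in 16, spots 955 and 956 in 11, spots 93 and 94 in 9, PRKCE in 5, spots 67 and 68 in 2, spots 35 and 36 in 1, and spots 7 and 8 in 0 of 23. Centring on housekeeping or spiked probes and averaging probes of a gene were not run, for want of such named probes. Signal over background is unknown.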

Other observations

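The tests of dye, array set and scaling, and those on the carbachol change in animals 4 and 5, were chosen after the results were seen; the relabelling tests were planned. The stretch changes in saline and in carbachol, from different strips of the same animals, correlated at 0.64 (Pearson) and 0.16 (Spearman) across 190 features, which are not independent replicates. Without the 6 called features the Pearson value was 0.14. The carbachol changes in unstretched and stretched strips correlated at -0.10. In animals 1, 4 and 5, saline stretched strips shared arrays with carbachol unstretched strips. In animals 4 and 5, saline unstretched strips also shared arrays with carbachol stretched strips. An effect of an array on a spot then enters the 2 correlated changes with opposite signs. The correlation to be met without any response was not computed.

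The rise of 6 features with stretch was set against technical explanations. The change of each feature was at least 0.666 of its main value in either dye alone. Since each RNA was labelled once with each dye, a constant dye bias of a spot cancels in either dye alone and in their mean. The values from 1 dye therefore do not test dye bias. With 1 channel the calls were lost for PRKCE (adjusted p = 0.248), spots 955 and 956 (0.0923) and spots 93 and 94 (0.121) in Cy5, and for spots 93 and 94 in Cy3 (0.367). An effect of the array set would leave a set without the rise, but 12 of 12 means over feature and set were above 0, 1 of them (spots 7 and 8) from animal 5 alone. This restates the rise of each feature in every animal measured and is not a separate test. Scaling would remove it from unscaled values, where each change was at least 1.03 of its main value, although spots 93 and 94 lost the call (adjusted p = 0.203). Spots 955 and 956 and spots 93 and 94 also lost it with median centring (adjusted p = 0.0686 and 0.259, log2 changes of 1.19 and 0.37) and quantile normalization (0.103 and 0.211, changes of 0.97 and 0.38), against main changes of 1.22 and 0.42. A response of these transcripts to stretch is therefore a hypothesis that these tests leave standing, found and tested on the same data.

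Treatment labels were also exchanged at random within animals, in 100 arrangements including the real one. For stretch, 1 arrangement of 100 gave 6 calls or more, and the highest other count was 4. For both against control 1 gave 7 or more, with a highest other count of 2. For stretch in saline 3 gave 4 or more (highest other 6), and for stretch in carbachol 3 gave 2 or more (highest other 4). Each of these 4 counts passed the 0.05 level taken singly, with no correction for the number of counts tested. For stretch in saline and stretch in carbachol, other arrangements gave more calls than the real one. The 4 counts also share strips and are not independent. The exchange ignored which strips shared arrays. Other arrangements can therefore turn a comparison within arrays into one between arrays, or the reverse, so their counts are only an approximate reference. For carbachol, the interaction, carbachol in unstretched strips and carbachol in stretched strips the real count was 0, which any arrangement reaches, so the 100 of 100 found was fixed in advance and says nothing about chance. The highest other counts were 8, 6, 3 and 9.

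In unstretched strips of animals 4 and 5, carbachol went with higher values of 3 of the stretch-raised pairs, with mean log2 changes of 2.08 for spots 67 and 68, 1.65 for spots 35 and 36 and 0.84 for spots 955 and 956, against 0.30, 0.15 and 0.14 in animals 1 to 3. For spots 955 and 956 the mean rests on animal 4, at 1.39, since animal 5 was at 0.279 and animal 1 at 0.321. A candidate explanation is a carbachol response that differs between animals, but the smallest adjusted p of the difference over the 3 pairs was 0.367 in limma, which leaves it open. Stretched RNA in those columns alone, as by a wrong label, also predicts the change of the other 3 called features. Leakage between channels is not described by that prediction. On arrays 13 to 20 the saline unstretched strips also shared their arrays with stretched strips, and the prediction takes them as free of stretched RNA. Observed minus predicted was -0.23 ± 0.127 on average (SE, 5 values): -0.32 and -0.338 for PRKCE, 0.0172 and 0.0941 for spots 93 and 94, and -0.60 for spots 7 and 8 in animal 5, the value that weighs most in the mean. With 2 animals on arrays of their own, where this change could be read only between arrays, these explanations cannot be told apart.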
